A study of Mus musculus with 150 samples.

How the data were processed

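Total RNA of mouse pancreatic ductal organoids grown in Matrigel domes was sequenced on DNBSEQ, per the labels' protocols. The 150 libraries were grouped by line, medium, week and batch as the labels give them. The tools FastQC 0.11.5, Trim Galore 0.4.4 and Salmon 1.3.0 and the builds GRCm38.p6 and mm10 are named, per the submitters' processing notes, without their order or the gene annotation. The authors deposited 1 file of expected counts per library, rounded to whole numbers per Ensembl gene and not scaled between libraries. They also deposited 1 file of TPM values per library, scaled within it. Both kinds held 54347 genes. Gene symbols (54094 genes), gene types and positions were taken from GENCODE M21. Every file matched a label. Depth ranged from 33167713 to 46656797 counts per library (median 37967647.5).

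Counts were analysed in R 4.3.3 with edgeR 4.0.16. Batches 1 and 2 (72 libraries) and batch 3 (78 libraries) were fitted apart, with 1 mean per group. Genes were kept by filterByExpr (19065 and 18374), libraries were scaled by TMM, and each contrast was tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. Contrasts over several weeks weigh the weeks equally. Standard errors are the fold change divided by the square root of F. CPM values use TMM library sizes, and log2 CPM a prior count of 2. Where every library of a group read 0, the fold is only a lower bound. The 27 gene lists were tested on log2 CPM with camera of limma 3.58.1, with an inter-gene correlation of 0.01 and again with a correlation estimated per list, adjusted over the lists of each contrast.

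The comparisons were acid against control at pH 6.7, at pH 7 and at week 8, return against acid, return against control, the differences of the acid response between lines, lines against each other in controls, and controls of week 8 against week 1. The contrasts of batch 3 at pH 7 were added after the files were seen.

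The lists, written before the data were examined, were cholesterol synthesis and uptake, fatty acid synthesis and desaturation, fatty acid oxidation, glycolysis and lactate export, tricarboxylic acid cycle and respiratory chain, proton and bicarbonate transport and acid sensing, lysosome and vacuolar ATPase, hypoxia response, integrated stress response, endoplasmic reticulum chaperones, Nrf2 detoxification, DNA replication, mitosis, p53 target genes, Kras and MAPK output, interferon-stimulated genes, NF-kB and inflammatory mediators, ductal identity, gastric and mucinous markers, basal-like and squamous markers, epithelial-mesenchymal transition, drug transport and nucleoside analogue metabolism, and markers of acinar, endocrine, fibroblast and stellate, immune and endothelial cells. The symbols Atp5f1a, Atp5f1b, Atp5f1c, Atp5po, Ero1a and Amy2a2 were not found among the symbols.

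Named genes follow a rule also written before the data were examined: Trp53, Kras, Cdkn1a, Mdm2, Slc9a1, Slc4a4 and Car9 always (1 further gene of the rule is not reported here); per contrast the 6 highest and 6 lowest folds among genes that passed, with at least 5 CPM in a compared group, the same sign in every week and no predicted name; and up to 4 passing members per list. The text prints a selection of them.

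Alternatives chosen before the data were examined were DESeq2 1.42.0, RLE factors, no filter, a stricter filter (5 CPM in 3 libraries), limma-trend on log2(TPM + 1), a fit on the compared libraries alone, each library left out in turn, single weeks, and a batch term over the 3 batches. Alternatives chosen after the files were seen were protein-coding genes alone, weeks 10 and 11 of controls and of batch 3 acid, counts summed per culture, and such sums with culture as a block. Groups were also split at random, at most 100 times each. Of the 6 ways to pair 2 groups of libraries, the number order gave the highest correlation in 8 of 8 pairs of acid and return groups of the same week (mean correlation 0.63, lowest 0.229). Between acid and control groups of the same week this held in 3 of 12 (mean 0.0584).

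Each test was checked on simulated counts with 50 genes changed per fold. In the mP4 acid contrast of batches 1 and 2 (19065 genes) edgeR recovered 33, 45, 48 and 50 of 50 at 1.5-, 2-, 3- and 4-fold and called 7 unchanged genes. At week 8 alone these were 10, 33, 44 and 48, and for the difference between lines 23, 37, 47 and 49. In the batch 3 mN10 contrast (18374 genes) they were 43, 47, 49 and 49. Camera detected a changed list of 30 genes in the mP4 contrast, and 0 of 20 unchanged lists passed.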

Results

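Mouse pancreatic ductal organoids of 4 lines were sequenced while their medium was slowly acidified. The lines were mN10 (wild type), mP4 (Kras G12D), p53KO (mP4 without Trp53) and p53R273H (mP4 with mutant Trp53). Per the labels, controls stayed at pH 7.4, acid cultures were at pH 7 in week 5 and at pH 6.7 in weeks 8, 10 and 11, and part of the acid cultures went back to pH 7.4 from week 9. The 150 libraries came in 3 batches of 36, 36 and 78. In batches 1 and 2 each mP4 and p53KO acid group of 3 had 3 controls of the same week, and week 1 had 6 controls per line. In batch 3 all 4 lines were present but controls were taken at week 1 alone (6, 3, 3 and 6 libraries), with 3 acid or return libraries per week for mN10 and p53R273H and 2 for mP4 and p53KO. Batch 3 acid contrasts therefore hold medium and weeks in culture together.

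Values after gene names are log2 fold changes with standard errors. Adjusted p of genes are from edgeR's quasi-likelihood test. They, like camera p, measure only the spread between libraries, which may be technical, and ignore repeated cultures. Batch 1 libraries fell into 3 sets that differ in how reads were assigned to near-identical genes. The mP4 contrasts at weeks 5 and 8, the genotype contrast at those weeks and week 8 against week 1 controls of both lines set 1 such set against another, and wider mP4 and genotype contrasts that hold those weeks do so in part. In batch 3 the marker Gm14760 differed between and within weeks (week 11 p53KO 7.29 to 8.82 CPM on return, 1.36 to 1.73 in acid). Acid and return contrasts there cross such a difference in part. For gene lists the median log2 fold change is followed by genes passed higher, passed lower and not passed, and after "alone" by the passing numbers when adjusted over the list alone. A number after a group, as in week 8 control 2, is a library's place in the number order of that group, and counts given with it are those of the fit without that library where it moved the count by more than 1.5 times. "In at least 7 of 9 libraries" counts treated or altered libraries on the side of the change. Trp53, the gene that was removed, averaged 222 ± 34.4 CPM (SD, n = 24) in mN10, 131.2 ± 46.2 in mP4 (n = 51), 25 ± 9.92 in p53KO (n = 51) and 21.4 ± 8.73 in the line labelled p53R273H (n = 24). The remaining signal in p53KO is transcript from a gene at chromosome 11, 69580359 to 69591873 (GRCm38), and the line labelled p53R273H was no higher. On the 2000 most variable genes component 1 held 46.8% of the variance and separated p53KO (-80.5 to -36.1) and p53R273H (-82.6 to -53.5) from mP4 (5.89 to 105) and mN10 (27.1 to 62.4).

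**Figure D1:**
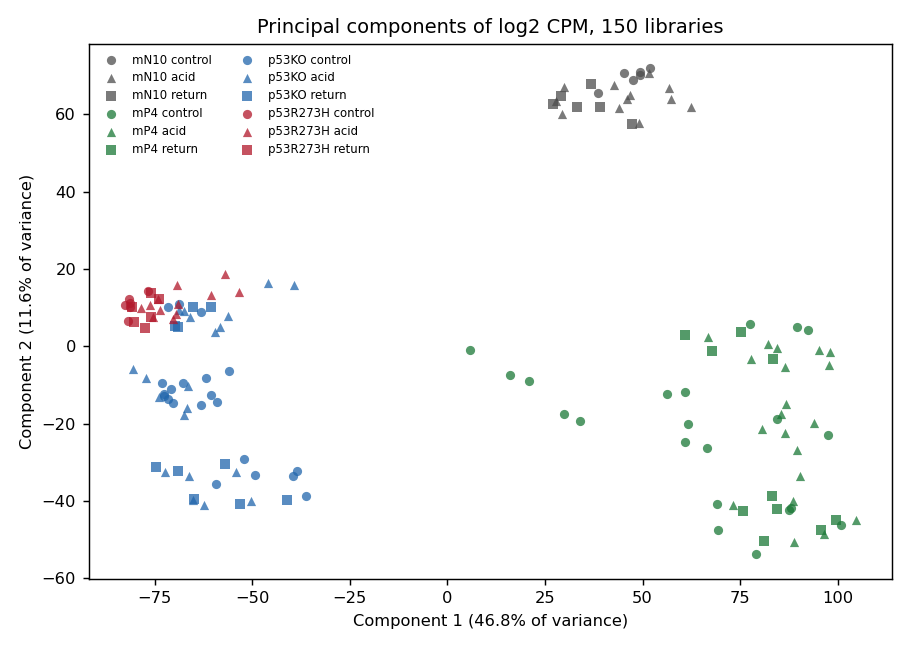
Principal components of log2 CPM for all libraries, coloured by line and medium.

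**Figure D2:**
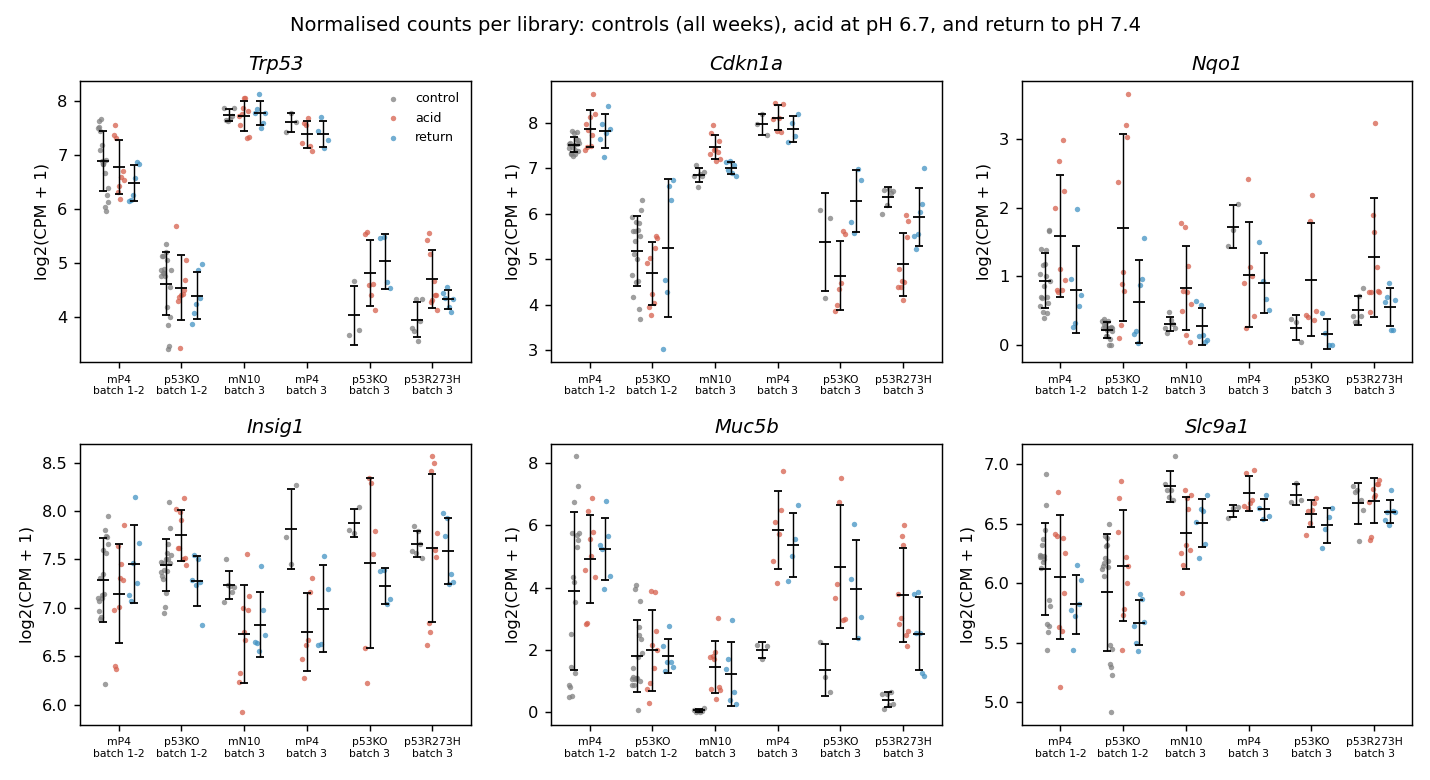
Levels of 6 genes in each library by line and batch, with mean and SD of control, pH 6.7 and return groups.

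Before any acid p53KO was set against mP4 in controls of batches 1 and 2 (18 libraries per line, 5 weeks). With 1 line each, Trp53 loss and line are not separated. Trp53 was lower in p53KO, -2.25 ± 0.12. Genes that p53 switches on were lower with it: the cell-cycle inhibitor Cdkn1a (-2.24 ± 0.17), the p53 ubiquitin ligase Mdm2 (-2.03 ± 0.06), cyclin Ccng1 (-3.82 ± 0.08), the death receptor Eda2r (-7.88 ± 0.27) and the stress sensor Sesn2 (-1.74 ± 0.10). The bicarbonate cotransporter Slc4a4 (-1.10 ± 0.23), the drug efflux pump Abcg2 (-2.21 ± 0.19), the chemokine Ccl2 (-3.75 ± 0.44) and the calcium hormone Stc1 (-4.502 ± 0.37) were lower too, and the proton-sensing receptor Gpr4 stood at 0.121 against 1.52 CPM. Higher in p53KO were the paracellular channel Cldn15 (7.92 ± 0.25), the cytokine Il1a (4.95 ± 0.40), the goblet lectin Zg16 (4.22 ± 0.58), the sodium-proton exchanger Slc9a2 (2.89 ± 0.31), the stress pseudokinase Trib3 (2.59 ± 0.33) and the hypoxia genes Ndrg1 (1.87 ± 0.27) and Ero1l (1.56 ± 0.21). So were phosphofructokinase Pfkp (1.54 ± 0.17), the endoplasmic reticulum factor Manf (1.26 ± 0.09) and the replication helicase Mcm5 (0.96 ± 0.19). Calcb (14.4 against 0.0736 CPM), Hoxa5 (3.5 against 0 CPM) and Hoxa3 (6.72 against 0.00587 CPM), a neuropeptide and 2 regional transcription factors on chromosome 6, were near 0 in mP4. By edgeR the lower genes had adjusted p from 3.23e-41 to 3.57e-05, in at least 16 of 18 libraries, the higher ones adjusted p from 1.74e-33 to 2.05e-05, in at least 17 of 18 libraries, and the Hoxa genes adjusted p from 4.01e-25 to 6.85e-22, in all 18 libraries.

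11627 of 19065 genes passed, 5964 higher and 5663 lower. The p53 target list was the strongest group: median -1.83, 0 higher, 26 lower, 4 not, alone 0 and 26, camera adjusted p = 1.9e-20, adjusted p = 7.71e-07 with an estimated correlation. Mitosis genes were higher (median 0.72, 25 higher, 0 lower, 3 not, alone 25 and 0, camera adjusted p = 2.49e-06, adjusted p = 0.602 with an estimated correlation). So was the Atf4-driven stress list (median 1.07, 21 higher, 2 lower, 2 not, alone 21 and 2, camera adjusted p = 8.77e-05, adjusted p = 0.602 with an estimated correlation). The Nrf2 antioxidant list was lower (median -0.52, 4 higher, 21 lower, 4 not, alone 4 and 21, camera adjusted p = 2.49e-06, adjusted p = 0.121 with an estimated correlation). Basal-like markers did not pass (median 1.06, 11 higher, 5 lower, 2 not, alone 11 and 5, camera adjusted p = 0.101, adjusted p = 0.685 with an estimated correlation).

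The same contrast in batch 3 (3 week 1 controls per line) shares no library with it. Trp53 was -3.58 ± 0.21 in p53KO, Cdkn1a (-2.41 ± 0.29), Mdm2 (-2.18 ± 0.12) and Sesn2 (-2.29 ± 0.17) were lower, and so were the MAPK phosphatase Dusp6 (-2.18 ± 0.19) and Ccl2 (-7.49 ± 0.64). The mucus protein Fcgbp (9.49 ± 0.90), the lectin Zg16 (9.71 ± 1.32), the trefoil peptide Tff3 (8.88 ± 1.07), the membrane mucin Muc13 (7.44 ± 0.92), the chloride channel Cftr (4.55 ± 0.54) and the mitophagy gene Bnip3 (3.29 ± 0.51) were higher. By edgeR the lower genes had adjusted p from 2.46e-21 to 6.72e-10, in all 3 libraries and the higher ones adjusted p from 9.93e-13 to 4.55e-07, in all 3 libraries. 8182 of 18374 genes passed, 4260 higher and 3922 lower. Between the batches 2814 genes were higher in both (1360 expected if independent), 2790 lower in both (1190 expected), and the fold changes of coding genes correlated at r = 0.82. The p53 target list was lower again: median -1.70, 0 higher, 24 lower, 5 not, alone 0 and 24, camera adjusted p = 4.56e-17, adjusted p = 9.71e-06 with an estimated correlation. Kras and MAPK output genes were lower (median -0.83, 0 higher, 13 lower, 11 not, alone 0 and 13, camera adjusted p = 0.000103, adjusted p = 0.452 with an estimated correlation). The 6 Y-linked genes measured were near 0 in both p53 lines (Ddx3y 0.0197 ± 0.0488 CPM in p53KO and 0.0588 ± 0.151 in p53R273H against 56 ± 31.9 in mP4), so Y-linked transcripts differ between the lines beside Trp53.

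Whether the line labelled p53R273H differs from p53KO was asked at week 1 of batch 3 (6 against 3 libraries). Trp53 (-0.14 ± 0.16, adjusted p = 0.752 by edgeR) and Cdkn1a (0.80 ± 0.24, adjusted p = 0.0605 by the same edgeR test, 82.9 against 47.5 CPM) did not pass. The proton channel Hvcn1 (3.22 ± 0.56) was higher, and the phosphatidate phosphatase Lpin1 (-0.93 ± 0.15), the adhesion molecule Icam1 (-1.09 ± 0.26), the matrix protein Thbs1 (-1.28 ± 0.24) and the guidance receptor Robo1 (-3.57 ± 0.61) were lower, by edgeR with adjusted p from 8.49e-05 to 0.00764, in all 6 libraries. 497 of 18374 genes passed, 75 higher and 422 lower. The count became 819, 243 and 320 without p53KO week 1 control 1, 2 and 3.

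mP4 was set against mN10 at week 1 of batch 3 (3 against 6). With 1 line each, Kras and line are not separated. Trp53 did not differ, -0.13 ± 0.16 (adjusted p = 0.545 by edgeR). The prostaglandin synthase Ptgs2 (4.78 ± 0.65), the mucin chaperone Agr2 (4.26 ± 0.55), the iron-binding Lcn2 (3.98 ± 0.64) and the stress cytokine Gdf15 (2.90 ± 0.37) were higher in mP4, with the Ras pathway brakes Spry4 (2.08 ± 0.27) and Dusp6 (1.75 ± 0.15), and with Cdkn1a (1.14 ± 0.23), Mdm2 (0.78 ± 0.10) and Kras (0.56 ± 0.10). Gpr4 stood at 5.05 against 0.0697 CPM. The duct keratin Krt19 (-1.37 ± 0.26), the proliferation marker Mki67 (-1.43 ± 0.35), carbonic anhydrase Car2 (-1.55 ± 0.26), succinate dehydrogenase Sdha (-0.70 ± 0.07) and the trefoil peptides Tff1 (-7.54 ± 1.04) and Tff3 (-6.87 ± 0.96) were lower. By edgeR the higher genes had adjusted p from 8.32e-14 to 6.35e-05 and the lower ones adjusted p from 1.99e-11 to 0.00076, each in all 3 libraries. 7000 of 18374 genes passed, 3602 higher and 3398 lower. Kras and MAPK output was higher (median 0.39, 10 higher, 0 lower, 14 not, alone 10 and 0, camera adjusted p = 0.00304, adjusted p = 0.634 with an estimated correlation). So were p53 targets (median 0.44, 15 higher, 0 lower, 14 not, alone 16 and 0, camera adjusted p = 0.000319, adjusted p = 0.245 with an estimated correlation).

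What growth at pH 6.7 does to mP4 was asked against controls of the same weeks (9 against 9 libraries, weeks 8, 10 and 11). Trp53 did not pass, 0.30 ± 0.15, nor did Cdkn1a (0.34 ± 0.22), the sodium-proton exchanger Slc9a1 (0.06 ± 0.08) or carbonic anhydrase Car9 (-0.41 ± 0.26). The neurite protein Nrn1 (4.503 ± 0.72), the cytochrome Cyp2d26 (2.505 ± 0.59), the lipoprotein cofactor Apoc2 (2.06 ± 0.35), the mitotic p53 regulator Gtse1 (0.60 ± 0.15), the liver and pancreas factor Hnf1a (0.56 ± 0.12) and the p53 target Zmat3 (0.27 ± 0.07) rose. The imprinted RNAs Meg3 (2.6 against 0.0526 CPM) and Rian (3.29 against 0.124 CPM), on chromosome 12 (109541001 to 109661716), were nearly absent from controls. Both were higher still in week 1 controls, and lower in acid in batch 3. The trefoil peptide Tff3 (-4.76 ± 0.83), the secreted Clca1 (-4.48 ± 0.85), the acyl-CoA synthetase Acsm3 (-3.35 ± 0.65), the carbonic anhydrase-related Car8 (-1.67 ± 0.34), the stress factor Atf3 (-1.35 ± 0.33), the chaperones Hspa5 (-0.60 ± 0.14) and Hsp90b1 (-0.47 ± 0.09) and the lysosomal cholesterol exporter Npc1 (-0.51 ± 0.13) fell. By edgeR the fixed genes had adjusted p from 0.207 to 0.732, in at least 6 of 9 libraries, the risen genes adjusted p from 5.37e-05 to 0.011, in at least 7 of 9 libraries, the imprinted pair adjusted p from 3.06e-05 to 4.16e-05, in all 9 libraries, and the fallen genes adjusted p from 0.000179 to 0.00913, in at least 8 of 9 libraries.

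1407 of 19065 genes passed, 617 higher and 790 lower, of which 591 higher and 684 lower were coding when coding genes were tested alone. Limma on TPM (another tool and unit) gave 2432 higher and 359 lower, and edgeR with RLE factors 681 and 762. Endoplasmic reticulum chaperones fell as a group: median -0.28, 0 higher, 7 lower, 13 not, alone 0 and 12, camera adjusted p = 7.26e-08, adjusted p = 0.144 with an estimated correlation. Nrf2 targets rose (median 0.25, 7 higher, 1 lower, 21 not, alone 12 and 1, camera adjusted p = 0.000281, adjusted p = 0.454 with an estimated correlation). Acinar markers did not pass (median -0.88, 0 higher, 2 lower, 7 not, alone 0 and 2, camera adjusted p = 0.115, adjusted p = 0.454 with an estimated correlation), nor did endocrine (median -0.03, 0 higher, 1 lower, 8 not, alone 0 and 1, camera adjusted p = 0.957, adjusted p = 0.977 with an estimated correlation) or endothelial ones (median 0.23, 0 higher, 0 lower, 11 not, alone 0 and 0, camera adjusted p = 0.287, adjusted p = 0.533 with an estimated correlation). Acid and return libraries at the same place in the number order of their groups resembled each other across weeks (26 of 30 pairs of groups, 5 expected), so they are probably the same cultures. With such libraries summed, 10 genes passed and 0 of the 16 named above. Week 8 alone gave 939, weeks 10 and 11 alone 287, and libraries left out 2192 without week 10 control 3 and 926 without week 11 control 1.

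The same medium was tested in p53KO (9 against 9 libraries). Trp53 did not pass, 0.31 ± 0.15 (adjusted p = 0.124 by edgeR, higher in 6 of 9 libraries). The caspase Casp1 (4.39 ± 0.46), the antiviral Oasl2 (2.70 ± 0.68), the calgranulin S100a8 (2.59 ± 0.69), the mucin Muc3 (4.17 ± 1.00), the homeobox factors Isx (3.83 ± 0.82) and Cdx2 (0.69 ± 0.22), the surface protein Tm4sf1 (3.72 ± 0.51) and Hnf1a (0.75 ± 0.12) rose. So did Slc9a1 (0.54 ± 0.08) and carbonic anhydrase Car12 (1.12 ± 0.29). The lysosomal regulator Tfeb (0.83 ± 0.15), the acetate ligase Acss2 (0.71 ± 0.17), phosphofructokinase Pfkm (0.66 ± 0.11), the integrin Itgb4 (0.65 ± 0.14) and the sterol enzymes Mvd (0.63 ± 0.16) and Pmvk (0.62 ± 0.11) rose too, and the quinone reductase Nqo1 stood at 3.78 against 0.138 CPM. The transcription factor Mef2c (-3.16 ± 0.52), osteopontin Spp1 (-1.31 ± 0.34), the collagen hydroxylase Plod2 (-1.17 ± 0.30), haem oxygenase Hmox1 (-0.72 ± 0.19), Manf (-0.66 ± 0.12) and the elongase Elovl5 (-0.58 ± 0.12) fell. By edgeR the risen genes had adjusted p from 5.43e-09 to 0.0149, in at least 7 of 9 libraries and the fallen ones adjusted p from 3.01e-05 to 0.00336, in at least 8 of 9 libraries.

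4937 of 19065 genes passed, 2482 higher and 2455 lower. Nrf2 targets rose: median 0.37, 15 higher, 1 lower, 13 not, alone 16 and 1, camera adjusted p = 2e-05, adjusted p = 0.369 with an estimated correlation. Interferon-stimulated genes rose (median 1.01, 17 higher, 1 lower, 12 not, alone 21 and 1, camera adjusted p = 2e-05, adjusted p = 0.752 with an estimated correlation). Cholesterol genes rose (median 0.18, 6 higher, 0 lower, 19 not, alone 6 and 0, camera adjusted p = 0.0259, adjusted p = 0.752 with an estimated correlation). Endoplasmic reticulum chaperones were lower (median -0.23, 2 higher, 9 lower, 9 not, alone 2 and 9, camera adjusted p = 0.00403, adjusted p = 0.752 with an estimated correlation), at weeks 10 and 11 alone (median -0.40) but not at week 8 (0.21). NF-kB targets did not pass as a list (median -0.55, 1 higher, 11 lower, 15 not, alone 1 and 11, camera adjusted p = 0.0728, adjusted p = 0.774 with an estimated correlation), with medians of 0.22 at week 8 and -0.98 at weeks 10 and 11, and proton and bicarbonate transport did not pass (median 0.22, 7 higher, 1 lower, 25 not, alone 7 and 1, camera adjusted p = 0.14, adjusted p = 0.752 with an estimated correlation). With libraries at the same place summed, 1 gene passed and 1 of the 23 named above. Week 8 alone gave 0.913% of genes, weeks 10 and 11 alone 4797, and this contrast's own libraries 2701.

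**Figure D3:**
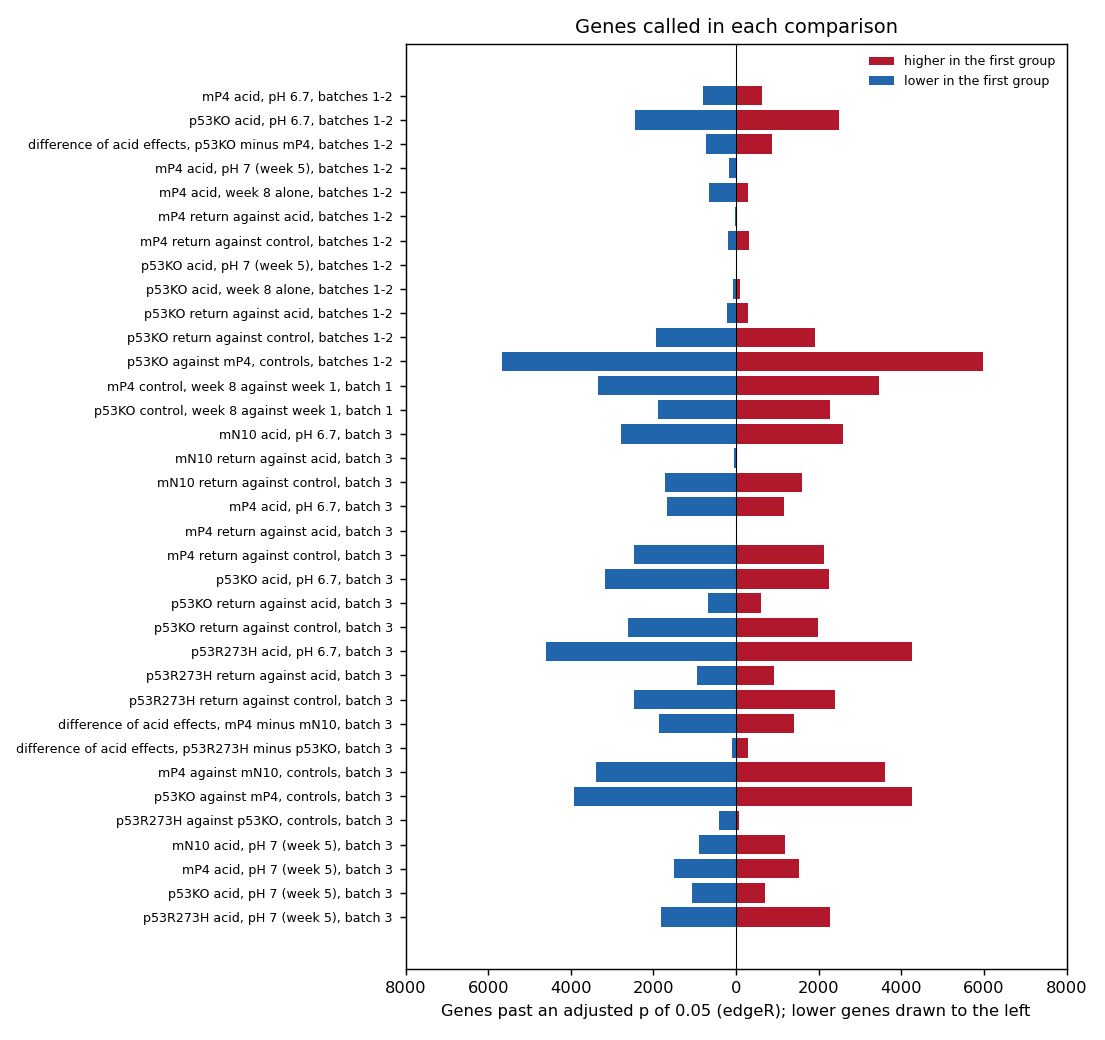
Genes passing in each comparison, split into higher and lower.

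Whether the 2 lines respond differently was tested as the difference of their acid contrasts (36 libraries). Trp53 did not differ, 0.01 ± 0.21 (edgeR adjusted p = 1, higher in 4 of 9). The response of p53KO exceeded that of mP4 for Casp1 (8.87 ± 1.10), Isx (6.69 ± 1.23), Muc3 (6.499 ± 1.33), Muc13 (4.01 ± 0.96), Clca1 (5.90 ± 1.10), Tff3 (5.42 ± 1.03), Car8 (2.70 ± 0.47), Tfeb (0.98 ± 0.22), the interferon factor Stat2 (0.84 ± 0.22) and Slc9a1 (0.48 ± 0.11). It fell short for Mdm2 (-0.38 ± 0.11), the death receptor Fas (-1.498 ± 0.41), the growth factor Nrg1 (-2.59 ± 0.54) and the cytokine Tgfb2 (-3.29 ± 0.60). By edgeR the first group had adjusted p from 1.46e-06 to 0.0127, in all 9 libraries, and the second adjusted p from 0.000446 to 0.0199, in at least 8 of 9 libraries (p53KO acid libraries). 1603 of 19065 genes passed, 875 higher and 728 lower. Interferon-stimulated genes responded more in p53KO (median 1.26, 7 higher, 0 lower, 23 not, alone 9 and 0, camera adjusted p = 6.17e-05, adjusted p = 0.821 with an estimated correlation). Its p53 targets responded less (median -0.14, 0 higher, 7 lower, 23 not, alone 1 and 8, camera adjusted p = 0.0155, adjusted p = 0.39 with an estimated correlation). Both contrasts called 248 genes higher (80.3 expected) and 231 lower (2.26 times the number expected), with r = -0.00441 over coding genes. Summing libraries at the same place, 21 genes passed and 1 of the 14 named.

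At pH 7 in week 5 (3 against 3 libraries) little protein-coding change was seen. In mP4 Trp53 was 0.16 ± 0.26 (edgeR adjusted p = 1, higher in 3 of 3). 0.918% of 19065 genes passed, 0.0315% higher and 0.886% lower, and 85.2% of the lower ones were processed pseudogenes (5.33% of tested genes). With coding genes alone edgeR called 0 of 14675, and 766 at unadjusted p < 0.05, while the stricter filter left 16. Omitted libraries made it 0.535% without week 5 acid 1 and 0.608% without week 5 control 3. In p53KO Trp53 was -0.09 ± 0.26 (edgeR adjusted p = 0.999, lower in 2 of 3). 1 gene passed by edgeR, with 1013 at unadjusted p < 0.05, 17 by DESeq2 and 40 by limma, and 0 and 0 without week 5 acid 1 and 2 and 0, 0 and 0 without week 5 control 1, 2 and 3. Fibroblast and stellate markers leaned lower (median -0.53, 0 higher, 0 lower, 9 not, alone 0 and 1, camera adjusted p = 0.0144, adjusted p = 0.165 with an estimated correlation). Mesenchymal genes leaned lower too (median -0.78, 0 higher, 0 lower, 16 not, alone 0 and 0, camera adjusted p = 0.00578, adjusted p = 0.37 with an estimated correlation).

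Week 8, the first week at pH 6.7 (3 against 3), was read apart. In mP4 the arms fall in different read-assignment sets, so this contrast holds set and medium together. Trp53 was 0.62 ± 0.26 (edgeR adjusted p = 0.155, higher in 3 of 3). The respiratory subunit Cox6c (-1.08 ± 0.13) was lower, as it was in week 8 controls of p53KO, which enter the same set without acid, and the skeletal RNA Dnm3os stood at 0.0805 against 9.24 CPM, with adjusted p from 1.65e-08 to 1.47e-06, in all 3 libraries by the same edgeR test. 939 of 19065 genes passed, 294 higher and 645 lower. Limma on TPM gave 4485 higher and 422 lower, and edgeR with RLE factors 282 and 660. Glycolysis genes were lower (median -0.67, 0 higher, 7 lower, 14 not, alone 0 and 15, camera adjusted p = 1.58e-08, adjusted p = 0.213 with an estimated correlation), but not at weeks 10 and 11 of 1 set (median 0.02, 0 passed lower). Its own libraries alone gave 43, and libraries left out 399 without week 8 acid 2 and 426 without week 8 control 3. In p53KO Trp53 was 0.05 ± 0.26 and Slc9a1 0.40 ± 0.14 (edgeR adjusted p = 0.961 and 0.133, higher in 1 and 3 of 3 libraries). 0.913% of 19065 genes passed, 0.556% higher and 0.357% lower. Proton transport genes leaned higher (median 0.31, 3 higher, 0 lower, 30 not, alone 4 and 0, camera adjusted p = 0.0314, adjusted p = 0.679 with an estimated correlation). Its own libraries alone gave 0, and libraries left out 1358, 15 and 11 without week 8 acid 1, 2 and 3 and 6, 2 and 1654 without week 8 control 1, 2 and 3.

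Week 8 controls differed from week 1 controls (3 against 6 libraries, batch 1), but fall in different read-assignment sets too. In mP4 Trp53 fell, -0.69 ± 0.23 (edgeR adjusted p = 0.0142, lower in 3 of 3). The vasodilator peptide Adm (3.74 ± 0.73), the growth factor receptor Csf1r (3.48 ± 0.77), the lactate exporter Slc16a3 (2.74 ± 0.66), the antiproliferative Btg2 (1.37 ± 0.19), Dusp6 (1.5 ± 0.24) and the duct factor Sox9 (1.03 ± 0.21) were higher at week 8. The methylation reader Uhrf1 (-2.04 ± 0.38), Mcm5 (-2.01 ± 0.43), the mitotic activator Cdc20 (-1.52 ± 0.33), fatty acid synthase Fasn (-1.31 ± 0.25) and the keratins Krt7 (-1.28 ± 0.23) and Krt8 (-1.17 ± 0.22) were lower. The imprinted genes of chromosome 12 were nearly lost: Meg3 (0.0755 against 19.8 CPM), Rian (0.0499 against 22 CPM) and the growth regulator Dlk1 (0.0577 against 9.65 CPM). By edgeR the higher genes had adjusted p from 1.76e-07 to 0.000907, in at least 2 of 3 libraries, the lower ones adjusted p from 1.83e-05 to 0.000263, in all 3 libraries and the imprinted ones adjusted p from 1.1e-05 to 0.00941, in all 3 libraries. 6789 of 19065 genes passed, 3453 higher and 3336 lower. DNA replication genes were lower (median -1.25, 0 higher, 28 lower, 2 not, alone 0 and 30, camera adjusted p = 6.23e-12, adjusted p = 0.626 with an estimated correlation). Hypoxia genes were higher (median 1.13, 16 higher, 0 lower, 7 not, alone 17 and 0, camera adjusted p = 4.35e-05, adjusted p = 0.626 with an estimated correlation).

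In p53KO Trp53 was -0.06 ± 0.22 (edgeR adjusted p = 0.887, lower in 1 of 3). The mitochondrial coactivator Ppargc1a (3.37 ± 0.65), the duct factor Onecut1 (1.87 ± 0.43), Elovl5 (1.23 ± 0.18), the glutathione enzyme Gclm (0.72 ± 0.12), the proton pump subunit Atp6v0c (0.77 ± 0.11), pyruvate kinase Pkm (0.63 ± 0.15) and citrate lyase Acly (0.47 ± 0.12) were higher at week 8. The gluconeogenic Pck2 (-1.09 ± 0.24), the chaperone cofactor Sdf2l1 (-0.89 ± 0.18) and Cox6c (-0.86 ± 0.11) were lower. By edgeR the higher genes had adjusted p from 3.7e-07 to 0.00372, in all 3 libraries and the lower ones adjusted p from 7.38e-08 to 0.000475, in all 3 libraries. 4156 of 19065 genes passed, 2261 higher and 1895 lower. Between the lines 586 genes were higher in both (410 expected) and 410 lower in both (332 expected).

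Whether the change goes back at pH 7.4 was asked at weeks 10 and 11 (6 return, 6 acid, 6 control libraries per line). In mP4 Trp53 was 0.01 ± 0.18 (edgeR adjusted p = 1, higher in 2 of 6). The glutathione enzyme Gclm (-0.55 ± 0.10) fell on return (adjusted p = 0.00773 by edgeR, in 6 of 6), while Cdkn1a did not pass, -0.20 ± 0.27 (same edgeR test, adjusted p = 0.874, in 4 of 6). 38 of 19065 genes passed, 17 higher and 21 lower. The p53 target list was lower on return and held under both correlations: median -0.25, 0 higher, 1 lower, 29 not, alone 0 and 5, camera adjusted p = 1e-05, adjusted p = 0.0383 with an estimated correlation. Drug transport genes were lower (median -0.23, 0 higher, 0 lower, 27 not, alone 0 and 5, camera adjusted p = 0.0121, adjusted p = 0.0975 with an estimated correlation). With cultures as blocks 2397 genes passed, and libraries left out 20, 89 and 25 without week 10 acid 1, 2 and 3, 4 without week 11 acid 3, 14 without week 10 return 3 and 8 and 25 without week 11 return 1 and 2. Against controls Trp53 was 0.16 ± 0.18 (edgeR adjusted p = 0.729, higher in 3 of 6), Nrn1 (3.73 ± 0.85) was higher and Car8 (-2.12 ± 0.41) and the growth adaptor Grb10 (-2.12 ± 0.49) were lower, by the same edgeR test with adjusted p from 0.00434 to 0.0122, in all 6 libraries. 511 of 19065 genes passed, 316 higher and 195 lower. Fatty acid synthesis genes leaned higher (median 0.23, 2 higher, 0 lower, 18 not, alone 3 and 0, camera adjusted p = 0.00242, adjusted p = 0.771 with an estimated correlation). With libraries at the same place summed 0 passed, and libraries left out 235, 289 and 1067 without week 10 control 1, 2 and 3, 212, 331 and 310 without week 11 control 1, 2 and 3, 279 and 237 without week 10 return 2 and 3 and 234 and 278 without week 11 return 1 and 2. Of 548 genes changed at least 2-fold at week 8, 435 of them lower, the median later acid shift was 0.24 and the median return shift 0.178, a ratio of 0.743 (SD 0.352 over libraries), and 1 gene was called back. These genes, 89 of them pseudogenes, were chosen where the sets differ, so the ratio does not measure how far an acid change went back.

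In p53KO Trp53 was -0.05 ± 0.18 (edgeR adjusted p = 0.95, lower in 3 of 6). The endosomal proton exchanger Slc9a9 (1.67 ± 0.31) rose on return and Nqo1 went from 4.93 to 0.669 CPM, by edgeR with adjusted p from 0.00154 to 0.00605, in all 6 libraries. 531 of 19065 genes passed, 299 higher and 232 lower. Atf4-driven stress genes rose (median 0.78, 9 higher, 0 lower, 16 not, alone 22 and 0, camera adjusted p = 5.88e-16, adjusted p = 0.258 with an estimated correlation). Mitosis genes fell (median -0.62, 0 higher, 4 lower, 24 not, alone 0 and 23, camera adjusted p = 4.99e-17, adjusted p = 0.278 with an estimated correlation). Nrf2 targets fell (median -0.33, 0 higher, 5 lower, 24 not, alone 1 and 9, camera adjusted p = 1.17e-05, adjusted p = 0.258 with an estimated correlation). With cultures as blocks 1626 genes passed, and libraries left out 0.934% without week 10 acid 2, 0.844% without week 11 acid 1, 0.991% without week 10 return 3 and 1.02% without week 11 return 3. Against controls Trp53 was 0.39 ± 0.18 (edgeR adjusted p = 0.133, higher in 5 of 6). Casp1 (4.11 ± 0.56), Isx (4.09 ± 1.03), the acute-phase Saa3 (3.46 ± 0.73), Tfeb (0.93 ± 0.19), Slc9a1 (0.39 ± 0.10) and phosphofructokinase Pfkl (0.59 ± 0.15) were higher, and Mef2c (-3.05 ± 0.63), Elovl5 (-0.78 ± 0.15) and the sterol desaturase Sc5d (-0.58 ± 0.16) lower. By edgeR the higher genes had adjusted p from 2.04e-06 to 0.00378, in at least 5 of 6 libraries and the lower ones adjusted p from 0.000183 to 0.00576, in at least 5 of 6 libraries. 3856 of 19065 genes passed, 1920 higher and 1936 lower. Summing libraries at the same place, 1 passed, and libraries left out 2471 without week 11 return 2. Of the genes changed at least 2-fold at week 8 the median later acid shift was 0.774 and the return shift 0.355, a ratio of 0.459 (SD 0.273), with 10 called back and 0 away. That ratio rests on few genes: it was 1.17 without week 8 acid 3 (10 genes), 1.14 without week 8 control 1 (6 genes) and -1.57 without week 8 control 2 (2 genes).

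In batch 3 wild-type organoids at pH 6.7 (9 libraries, weeks 8, 10 and 11) were set against 6 week 1 controls. Trp53 did not pass, -0.01 ± 0.12 (adjusted p = 0.952 by edgeR, lower in 4 of 9), but its targets rose: Cdkn1a (0.63 ± 0.18), Mdm2 (0.45 ± 0.07), Sesn2 (0.39 ± 0.11) and the apoptosis activator Pmaip1 (1.34 ± 0.16). The iron carrier Trf (5.88 ± 0.72), the prostaglandin enzymes Ptges (4.91 ± 0.59) and Ptgs2 (2.60 ± 0.54), the basal keratin Krt5 (3.86 ± 0.45), Car8 (3.38 ± 0.46), the cystine importer Slc7a11 (2.77 ± 0.34), Trib3 (1.94 ± 0.38), the glutathione ligase Gclc (1.67 ± 0.13), Bnip3 (1.32 ± 0.33) and Sox9 (0.57 ± 0.10) rose. The sterol enzymes Sc5d (-0.38 ± 0.06), Hsd17b7 (-0.89 ± 0.15) and Tm7sf2 (-1.10 ± 0.13), the proton exporter Slc9a1 (-0.39 ± 0.08), the chaperone Calr (-0.70 ± 0.10), Car9 (-1.53 ± 0.40), the plasma protein Ambp (-3.68 ± 0.42) and Tff3 (-3.94 ± 0.51) fell. The risen genes had adjusted p from 2.04e-14 to 0.00536, in at least 7 of 9 libraries by edgeR and the fallen ones adjusted p from 1.78e-09 to 0.00225, in at least 8 of 9 libraries. 5368 of 18374 genes passed, 2577 higher and 2791 lower. The p53 target list rose and held under both correlations: median 0.40, 18 higher, 2 lower, 9 not, alone 19 and 2, camera adjusted p = 4.25e-07, adjusted p = 0.0207 with an estimated correlation. Cholesterol genes fell (median -0.60, 0 higher, 22 lower, 3 not, alone 0 and 22, camera adjusted p = 3.93e-17, adjusted p = 0.0721 with an estimated correlation). Fatty acid oxidation genes fell (median -0.26, 1 higher, 13 lower, 9 not, alone 1 and 13, camera adjusted p = 0.00316, adjusted p = 0.483 with an estimated correlation). With libraries at the same place summed 2598 passed.

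In mP4 (6 acid, 3 control libraries) Trp53 did not pass, -0.23 ± 0.16 (adjusted p = 0.36 by edgeR, lower in 5 of 6), and Mdm2 (0.40 ± 0.10) rose (adjusted p = 0.00425 by edgeR's same test, 5 of 6). The gel-forming mucins Muc5b (4.39 ± 0.81) and Muc5ac (3.67 ± 0.76), the retinol enzyme Adh7 (3.43 ± 0.76), the cadherin Cdh2 (3.20 ± 0.73), the repair nuclease Ercc5 (0.92 ± 0.11), hexokinase Hk2 (0.85 ± 0.20) and the growth factor Hbegf (0.76 ± 0.14) rose, and Padi1 (2.67 against 0.0963 CPM), an arginine deiminase, appeared. The sterol sensor Insig1 (-1.11 ± 0.12), Hsd17b7 (-1.12 ± 0.19), the carnitine transferase Cpt1a (-0.74 ± 0.15), the Ras brake Spry2 (-0.65 ± 0.12) and Icam1 (-2.60 ± 0.26) fell. Nearly lost were Nid1 (0.0401 against 15 CPM), Pxdn (0.0757 against 12.9 CPM), Meg3 (0.0509 against 13.2 CPM) and Rian (0.0367 against 13.1 CPM). By edgeR the risen genes had adjusted p from 3.34e-08 to 0.0018, in all 6 libraries, the fallen ones adjusted p from 1.02e-10 to 0.000364, in all 6 libraries and the imprinted pair adjusted p from 6.11e-06 to 2.42e-05, in all 6 libraries. 2841 of 18374 genes passed, 1157 higher and 1684 lower. Cholesterol genes fell: median -0.60, 0 higher, 17 lower, 8 not, alone 0 and 21, camera adjusted p = 3.36e-13, adjusted p = 0.169 with an estimated correlation. p53 targets rose (median 0.21, 7 higher, 0 lower, 22 not, alone 7 and 0, camera adjusted p = 0.000655, adjusted p = 0.169 with an estimated correlation). Against the week-matched mP4 contrast 85 genes were higher in both (39.7 expected), and 1.83 times the 71.4 expected lower in both. Summing libraries at the same place, 75 passed and 4 of 18 named, and libraries left out 1604 without week 1 control 2.

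In p53KO (6 acid, 3 control libraries) Trp53 (0.74 ± 0.17) transcript rose. The receptor kinase Axl (4.38 ± 1.12), the neutrophil factor Csf3 (4.17 ± 0.90), Muc5ac (4.15 ± 0.73), Muc5b (3.70 ± 0.79), the matrix protein Tnc (4.09 ± 0.79), Stc1 (4.09 ± 0.76), the MAPK-driven Fosl1 (2.07 ± 0.44), Slc7a11 (2.03 ± 0.46), Gclc (1.42 ± 0.17) and the angiogenic Vegfa (1.16 ± 0.29) rose with it. Calr (-0.87 ± 0.13), lactate dehydrogenase Ldha (-0.95 ± 0.16), Muc1 (-0.96 ± 0.16), the lysosomal Gba (-1.17 ± 0.11) and Atp6v0d1 (-1.18 ± 0.14), Krt8 (-1.19 ± 0.21), the sterol enzymes Mvk (-1.30 ± 0.18) and Tm7sf2 (-1.87 ± 0.17), Cftr (-2.001 ± 0.38) and Zg16 (-3.69 ± 0.73) fell. The risen genes had adjusted p from 1.66e-08 to 0.00214, in all 6 libraries by edgeR and the fallen ones adjusted p from 7.57e-12 to 0.000108, in at least 5 of 6 libraries. 5436 of 18374 genes passed, 2251 higher and 3185 lower. Lysosome genes fell (median -0.33, 0 higher, 21 lower, 18 not, alone 0 and 21, camera adjusted p = 1e-07, adjusted p = 0.3 with an estimated correlation). Kras and MAPK output genes rose (median 0.46, 13 higher, 0 lower, 11 not, alone 13 and 0, camera adjusted p = 5.54e-06, adjusted p = 0.3 with an estimated correlation). Immune markers leaned higher (median 0.84, 4 higher, 0 lower, 5 not, alone 4 and 0, camera adjusted p = 0.0221, adjusted p = 0.335 with an estimated correlation). Against the week-matched p53KO contrast 306 genes were higher in both (306 expected), 389 lower in both (433 expected), and 640 higher there but lower here (435 expected), with r = -0.0903. With libraries at the same place summed 1279 passed.

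In the line labelled p53R273H (9 acid, 6 control libraries) Trp53 (0.77 ± 0.12) rose as well. Tnc (6.0 ± 0.64), Muc5b (5.22 ± 0.68), Muc5ac (3.25 ± 0.51), Car8 (3.73 ± 0.45), the macrophage factor Csf1 (2.92 ± 0.29), Fosl1 (1.31 ± 0.31), Slc4a4 (1.27 ± 0.24), Stat2 (0.76 ± 0.17) and laminin Lamc2 (0.79 ± 0.14) rose. The posterior regulators Hoxa9 (19.9 against 0.0283 CPM), Hoxa7 (7.83 against 0.0566 CPM) and Hoxa10 (29.1 against 0.311 CPM), side by side on chromosome 6 (52214491 to 52240854), came on. Krt8 (-0.98 ± 0.16), Gba (-0.93 ± 0.08), Ldha (-1.02 ± 0.12), Mvk (-1.19 ± 0.14), Sdf2l1 (-1.35 ± 0.14), Cdkn1a (-1.53 ± 0.17), Ero1l (-1.60 ± 0.24), Tm7sf2 (-1.62 ± 0.13), Zg16 (-3.82 ± 0.58) and the trefoil peptides Tff1 (-4.65 ± 0.52) and Tff2 (-3.90 ± 0.42) fell. By edgeR the risen genes had adjusted p from 1.53e-11 to 0.000402, in all 9 libraries, the Hoxa genes adjusted p from 9.58e-08 to 4.66e-07, in all 9 libraries and the fallen ones adjusted p from 1.22e-14 to 9.21e-07, in all 9 libraries. 8868 of 18374 genes passed, 4260 higher and 4608 lower. Respiratory genes fell (median -0.37, 1 higher, 26 lower, 7 not, alone 1 and 28, camera adjusted p = 1.07e-08, adjusted p = 0.441 with an estimated correlation). Endoplasmic reticulum chaperones fell (median -0.71, 0 higher, 16 lower, 4 not, alone 1 and 16, camera adjusted p = 1.03e-08, adjusted p = 0.374 with an estimated correlation). Duct identity genes fell (median -0.31, 1 higher, 9 lower, 10 not, alone 1 and 9, camera adjusted p = 0.0433, adjusted p = 0.441 with an estimated correlation). With p53KO 1774 genes were higher in both (522 expected) and 2515 lower in both (799 expected), though each line had its own controls. In all 4 lines 0.62% of genes rose (24.7 times expected) and 0.914% fell (15.1 times), 11 of them cholesterol genes. Weeks in culture are shared too, and week-matched p53KO cholesterol genes rose.

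**Figure D4:**
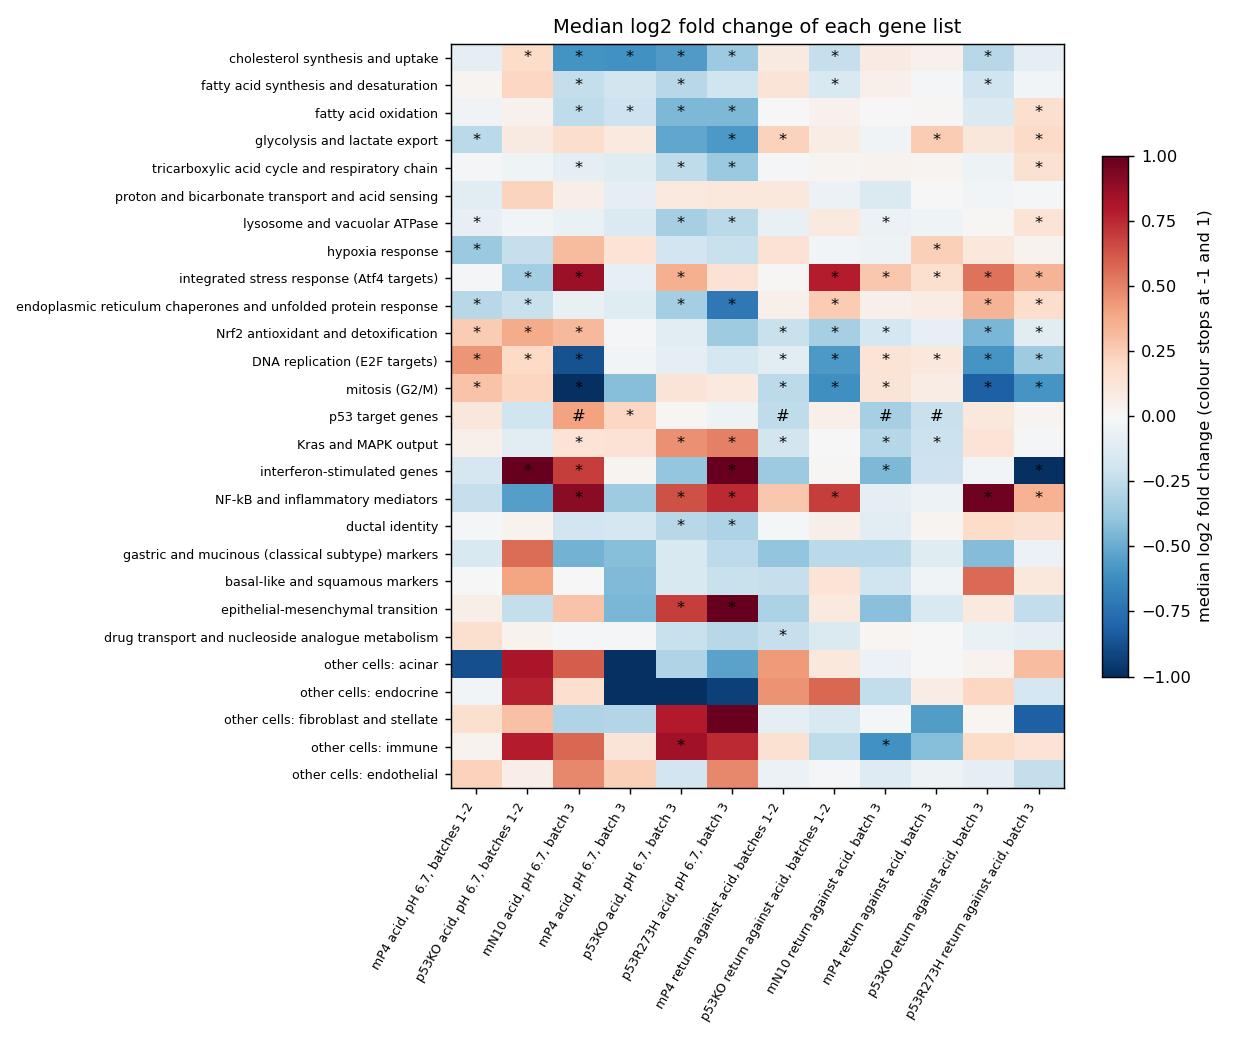
Median log2 fold change of 27 gene lists in 12 comparisons, starred where camera passed and marked # where it held with an estimated correlation.

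The batch 3 responses were also compared between lines. Trp53 did not differ, -0.21 ± 0.20 (edgeR adjusted p = 0.519, lower in 4 of 6). The mP4 response exceeded that of mN10 for the phosphate carrier Slc34a2 (4.62 ± 0.91), the mucosal Dmbt1 (4.17 ± 0.93), the gastric protease Ctse (3.01 ± 0.58), Krt19 (1.17 ± 0.31) and Slc9a1 (0.55 ± 0.13). It fell short for Sox9 (-0.89 ± 0.17), the secretory factor Xbp1 (-0.96 ± 0.19), the NF-kB brake Nfkbia (-1.001 ± 0.23), the apoptosis genes Bbc3 (-1.09 ± 0.22) and Pmaip1 (-1.49 ± 0.26), Slc7a11 (-3.78 ± 0.51), Car8 (-4.85 ± 0.71) and the small chaperone Hspb8 (-8.81 ± 0.83). By edgeR the first group had adjusted p from 0.000176 to 0.00555, in all 6 libraries and the second adjusted p from 2.12e-10 to 0.00141, in all 6 libraries (mP4 acid libraries). 3271 of 18374 genes passed, 1399 higher and 1872 lower. DNA replication genes differed most (median 0.72, 18 higher, 0 lower, 12 not, alone 26 and 0, camera adjusted p = 1.16e-14, adjusted p = 0.56 with an estimated correlation). Libraries left out gave 1849 without mP4 week 1 control 2. Trp53 was 0.03 ± 0.20 in the other test (edgeR adjusted p = 1, higher in 3 of 9). The line labelled p53R273H exceeded p53KO for the decoy receptor Tnfrsf11b (5.56 ± 0.84), the matrix genes Fbln1 (2.37 ± 0.48) and Thbs1 (1.84 ± 0.30) and the LDL receptor Ldlr (0.64 ± 0.13), with adjusted p from 1.87e-05 to 0.00218, in at least 6 of 9 libraries by edgeR, and fell short for Tff1 (-5.73 ± 0.93) and Tff2 (-5.38 ± 0.75), with adjusted p from 2.57e-06 to 4.43e-05, in all 9 libraries by the same edgeR test. 2.14% of 18374 genes passed, 1.58% higher and 0.555% lower. The count became 219 without p53KO week 1 control 2.

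Return to pH 7.4 in batch 3 was read against acid of the same weeks. In mN10 (6 against 6) Trp53 was 0.03 ± 0.13 (edgeR adjusted p = 0.984, higher in 4 of 6). The anion exchanger Slc4a2 (0.49 ± 0.08) rose (adjusted p = 0.000723 by edgeR, 6 of 6). Cdkn1a (-0.35 ± 0.19) and Mdm2 (-0.28 ± 0.08) did not pass (edgeR, adjusted p from 0.0998 to 0.53, in all 6 libraries). 69 of 18374 genes passed, 12 higher and 57 lower, and the p53 target list fell: median -0.33, 0 higher, 2 lower, 27 not, alone 0 and 10, camera adjusted p = 9.01e-12, adjusted p = 0.000325 with an estimated correlation. Cultures as blocks gave 884, and libraries left out 4 and 160 without week 10 acid 1 and 3, 36 and 41 without week 11 acid 1 and 3, 18 and 44 without week 10 return 2 and 3 and 28 and 34 without week 11 return 2 and 3. In mP4 (4 against 4) Trp53 was 0.03 ± 0.16 (edgeR adjusted p = 1, higher in 3 of 4), Cdkn1a -0.17 ± 0.23 and Mdm2 -0.30 ± 0.10 (edgeR, adjusted p from 0.455 to 0.974, in at least 2 of 4 libraries). edgeR called 0 genes with 1174 at unadjusted p < 0.05, DESeq2 29, limma 42 and edgeR with cultures as blocks 50, and 11 without week 11 acid 1. Here too the p53 list was lower (median -0.22, 0 higher, 0 lower, 29 not, alone 0 and 3, camera adjusted p = 1.01e-05, adjusted p = 0.0479 with an estimated correlation).

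In p53KO (4 against 4) Trp53 rose, 0.60 ± 0.16 (edgeR adjusted p = 0.0181, higher in 4 of 4). The stress cytokine Gdf15 (1.99 ± 0.41), the chemokine Cxcl2 (2.01 ± 0.44), the glutathione-degrading Chac1 (1.86 ± 0.40), Cdkn1a (1.32 ± 0.24), Hspa5 (0.93 ± 0.18), Npc1 (0.77 ± 0.16) and Slc4a2 (0.59 ± 0.10) rose. Hnf1a (-0.52 ± 0.10), Insig1 (-0.77 ± 0.13) and the steroid dehydrogenase Hsd11b2 (-2.38 ± 0.42) fell, and Nqo1 went from 1.69 to 0.127 CPM. The risen genes had adjusted p from 0.000175 to 0.00378, in at least 3 of 4 libraries by edgeR and the fallen ones adjusted p from 0.000195 to 0.00256, in all 4 libraries. 1286 of 18374 genes passed, 607 higher and 679 lower. Mitosis genes fell (median -0.81, 0 higher, 23 lower, 5 not, alone 0 and 28, camera adjusted p = 5.1e-19, adjusted p = 0.229 with an estimated correlation). Atf4-driven stress genes rose (median 0.55, 11 higher, 0 lower, 14 not, alone 15 and 0, camera adjusted p = 2.34e-12, adjusted p = 0.229 with an estimated correlation). With the week-matched p53KO return contrast 96 genes were higher in both (10.1 expected), 15.1 times the 8.7 expected lower in both and 0 opposite. Cultures as blocks gave 2132, and libraries left out 609 and 752 without week 10 acid 1 and 2, 390 without week 11 acid 2, 301 without week 10 return 2 and 305 and 791 without week 11 return 1 and 2.

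In the line labelled p53R273H (6 against 6) Trp53 was -0.05 ± 0.13 (edgeR adjusted p = 0.863, lower in 3 of 6). Slc9a9 (1.42 ± 0.28), the proton-coupled folate carrier Slc46a1 (1.14 ± 0.17), Cdkn1a (0.91 ± 0.20), Tm7sf2 (0.69 ± 0.14) and Atp6v0d1 (0.51 ± 0.12) rose on return. Ldlr (-0.43 ± 0.09), Insig1 (-0.48 ± 0.10), the mitotic kinesin Kif23 (-0.54 ± 0.14), the replication genes Cdc6 (-0.76 ± 0.21) and Mcm10 (-0.79 ± 0.18), Gclc (-0.86 ± 0.13), Nqo1 (-2.11 ± 0.56) and the interferon gene Trim30a (-2.83 ± 0.56) fell. By edgeR the risen genes had adjusted p from 2.01e-05 to 0.00352, in all 6 libraries and the fallen ones adjusted p from 6.99e-05 to 0.0141, in all 6 libraries. 1864 of 18374 genes passed, 916 higher and 948 lower. Interferon-stimulated genes fell (median -1.20, 0 higher, 19 lower, 11 not, alone 0 and 26, camera adjusted p = 9.5e-05, adjusted p = 0.679 with an estimated correlation). Mitosis genes fell (median -0.59, 0 higher, 13 lower, 15 not, alone 0 and 24, camera adjusted p = 4.68e-12, adjusted p = 0.64 with an estimated correlation). With p53KO 219 genes were higher in both (30.3 expected), 307 lower in both (35 expected) and 0 opposite. Over 3 return contrasts (p53KO in each set, p53R273H) 62 genes were higher in all (0.524 expected) and 100 lower in all (0.454 expected). Cultures as blocks gave 2652, and libraries left out 1183 without week 10 acid 2, 1062 without week 11 acid 1, 1093 without week 10 return 1 and 1016 without week 11 return 3.

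The returned cultures were also set against week 1 controls, which the acid contrasts share, with weeks in culture and medium held together. In mN10 Trp53 was 0.04 ± 0.13 (edgeR adjusted p = 0.897, higher in 4 of 6). Trf (4.67 ± 0.69), the hypoxia gene Ndrg1 (1.79 ± 0.34) and Gclc (1.06 ± 0.13) were higher with Spdef (3.76 against 0.058 CPM), a goblet factor, and Car9 (-1.76 ± 0.45), Tff3 (-4.17 ± 0.61) and Ambp (-4.25 ± 0.50) were lower. By edgeR these had adjusted p from 6.71e-10 to 0.000104, in at least 5 of 6 libraries, and adjusted p from 9.99e-09 to 0.00362, in all 6 libraries. 3308 of 18374 genes passed, 1586 higher and 1722 lower. In mP4 Trp53 was -0.21 ± 0.17 (edgeR adjusted p = 0.393, lower in 3 of 4). Adh7 (4.16 ± 0.81), Muc5b (3.81 ± 0.80), Hk2 (1.14 ± 0.21) and the ribonucleotide reductase Rrm2 (1.90 ± 0.27) were higher, and the stress factors Atf5 (-2.23 ± 0.35) and Nupr1 (-3.44 ± 0.75) and Icam1 (-3.01 ± 0.30) lower. By edgeR these had adjusted p from 4.98e-07 to 0.000319, in all 4 libraries, and adjusted p from 2.21e-10 to 0.000507, in all 4 libraries. 4601 of 18374 genes passed, 2119 higher and 2482 lower. Omitted libraries made it 2926 without week 1 control 1.

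In p53KO Trp53 (0.96 ± 0.18), Csf3 (5.53 ± 0.95), Fosl1 (3.03 ± 0.48), Gdf15 (2.69 ± 0.48) and Vegfa (1.96 ± 0.31) were higher, and Zg16 (-3.37 ± 0.84) and the drug pump Abcb1a (-3.5 ± 0.45) lower. By edgeR these had adjusted p from 5.13e-06 to 7.57e-05, in all 4 libraries, and adjusted p from 9.93e-08 to 0.00209, in all 4 libraries. 4607 of 18374 genes passed, 1982 higher and 2625 lower. In the line labelled p53R273H Trp53 was 0.37 ± 0.14 (adjusted p = 0.0344 by edgeR, 6 of 6), a call lost with the contrast's own libraries alone (edgeR adjusted p = 0.0641). Tnfrsf11b (4.85 ± 0.54), Thbs1 (2.21 ± 0.21) and Lpin1 (1.37 ± 0.13) were higher and Tff1 (-4.84 ± 0.62) and the iron reductase Cybrd1 (-5.91 ± 0.69) lower, by the same edgeR test with adjusted p from 1.5e-11 to 1.86e-09, in all 6 libraries, and adjusted p from 2.92e-09 to 2.99e-08, in all 6 libraries. 4866 of 18374 genes passed, 2404 higher and 2462 lower.

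Week 5 at pH 7 in batch 3 was added after the data were seen. In mN10 Trp53 was 0.21 ± 0.16 (edgeR adjusted p = 0.433, higher in 3 of 3). Ltbp2 (8.69 against 0.0351 CPM), a matrix gene, and Lcn2 (4.79 ± 0.66) were higher and Tff3 (-6.78 ± 0.95) lower, by edgeR with adjusted p from 2.1e-10 to 1.55e-06, in all 3 libraries. 2077 of 18374 genes passed, 1182 higher and 895 lower. Inflammatory mediators rose under both correlations (median 1.12, 17 higher, 0 lower, 11 not, alone 22 and 1, camera adjusted p = 2.04e-17, adjusted p = 0.0222 with an estimated correlation). Gastric markers fell (median -0.72, 0 higher, 5 lower, 16 not, alone 1 and 11, camera adjusted p = 1.34e-06, adjusted p = 0.0446 with an estimated correlation). Libraries left out gave 1211 and 779 without week 5 acid 2 and 3. In mP4 Trp53 was -0.41 ± 0.21 (edgeR adjusted p = 0.175, lower in 2 of 2). The plasminogen activator Plau (3.21 ± 0.45) and Thbs1 (2.04 ± 0.31) were higher, by edgeR with adjusted p from 1.53e-06 to 7.7e-06, in all 2 libraries. 3024 of 18374 genes passed, 1523 higher and 1501 lower. The count became 909 and 698 without week 5 acid 1 and 2 and 1465 without week 1 control 2. In p53KO Trp53 was 0.34 ± 0.21 (edgeR adjusted p = 0.318, higher in 2 of 2). Tff2 (3.23 ± 0.67) was higher and Gba (-0.76 ± 0.15) lower, by edgeR with adjusted p from 0.00111 to 0.00224, in all 2 libraries. 1771 of 18374 genes passed, 710 higher and 1061 lower. Omitted libraries made it 814 and 25 without week 5 acid 1 and 2 and 792 without week 1 control 1. In the line labelled p53R273H Trp53 was 0.39 ± 0.16 (edgeR adjusted p = 0.0758, higher in 3 of 3). Muc5b (5.10 ± 0.75) and Ldlr (1.02 ± 0.10) were higher and Cdkn1a (-1.07 ± 0.25), Trib3 (-2.07 ± 0.52) and Chac1 (-1.96 ± 0.43) lower, by edgeR with adjusted p from 4.18e-10 to 0.00318, in all 3 libraries. 4081 of 18374 genes passed, 2262 higher and 1819 lower. Libraries left out gave 1640 and 2418 without week 5 acid 1 and 2.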

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

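Tests of read assignment, genomic DNA, drifting cultures and the Y chromosome were chosen after seeing the result, and the others before. In 4 groups of 4 to 10 libraries 40 values were tested and 4 stood apart, where chance marks about 1 in 20. In mP4 week 1 controls of batch 1, 1 library had 17.4% mitochondrial counts (the others 7.04 to 9.7). In mN10 week 1 controls 1 library, the same each time, had 1.4e+02 CPM of Mdm2 (the others from 91.2), 1.3e+02 of Slc9a1 (the others from 1.0e+02) and 73.5 of Slc4a4 (the others from 1.2e+02). No explanation was tested for these.

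By edgeR's test of the difference itself the acid response differed between lines in 1603 genes (p53KO against mP4, batches 1 and 2), 3271 (mP4 against mN10, batch 3) and 393 (p53R273H against p53KO, batch 3). With labels exchanged 3, 2 and 16 of 100 splits gave at least as many, so the last does not stand apart. These splits part libraries of probably the same culture, so the low shares of the others may come from cultures: summed per culture 21 and 499 passed. Batch 3 acid libraries at pH 7, which no comparison chosen before used, gave 2077 genes in mN10, 3024 in mP4, 1771 in p53KO and 4081 in p53R273H against week 1 controls. Weeks in culture and medium cannot be told apart there.

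The genes lower in mP4 acid cultures at pH 7 (median -2.98) were all lower in week 8 than in week 1 controls too (median -2.28, SD 1.41), which fits read assignment that differs between sets of libraries. Genomic DNA in the week 5 controls would push the folds of genes typed TEC or lincRNA below 0, and their median was 0. An effect of the medium stays open: at weeks 10 and 11 the median was -0.11 (SD 0.719), with 97 genes lower.

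In p53KO of batches 1 and 2 the acid calls may come from parallel cultures drifting apart, but no value settles it. With each culture's weeks summed 0.0203% of them (1 of 4937) still passed. Their median fold was 0.47 (median SE 0.12) before and 0.45 (0.16) after, and 64.1% kept unadjusted p < 0.05 in edgeR. So folds stayed and the spread widened. In simulations of the same layout (mP4 acid) sums cost no calls (88% both ways), which argues against fewer units as cause. They cost some in another (mP4 less mN10, 78% to 64.5%). Against batch 3 the correlation over 14282 coding genes was -0.09, and 0.17 (Spearman 0.14) with the week 1 to 8 change subtracted. Both sides share week 8 controls, so 0.17 decides nothing. Time in culture and medium stay open. In batch 3 the called genes had a signed median of -0.05 on return (-0.09 at week 10, -0.01 at week 11), 57.5% of 4871 went back, and 47% shared their sign under acid.

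Y-linked genes were near 0 in p53KO and p53R273H. Xist, at most 0.748 CPM in their libraries, argues against a female source. Ddx3y (0 libraries on the wrong side of 5 CPM) restates the pattern, so mislabelling stays open. Loss of the Y chromosome cannot be told apart from silencing by transcripts: over 6 genes and both lines the highest ratio to mP4 was 0.00789. No consequence was tested.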

How the results depend on the processing

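Most alternatives were chosen before the data were examined. The later ones listed above and all batch 3 contrasts at pH 7 came after. In all, 216 of 313 alternative counts stayed within 1.5 times the reported one, 97 did not, and no named gene reversed. RLE factors kept all 35 counts and the batch term all 3. Of 359 named gene results 355 kept side and direction with DESeq2, 358 with RLE factors and 350 with limma on TPM. With no filter 357 did, and with the compared libraries alone 338. With 1 library left out 5225 of 5307 did, while 100 of 210 no longer passed with sums per culture. In p53KO acid, batches 1 and 2, the called genes' median fold was 0.47, then 0.45 with such sums, which keep a fold whatever its cause. Its median SE rose from 0.12 to 0.16. The limits are linked: acid and return libraries of the same place at several weeks are probably the same cultures, which leaves 3 or 2 per arm, and in batch 3 week and medium are confounded. Of 12 pairs of control groups 8 matched by place too (2 expected), so controls may also be repeated cultures. Depth was not varied: 3 counts equal 0.0843 to 0.0949 CPM by line, below which a level cannot be told from 0. Library number was: at 1.5-fold the simulated mP4 acid contrast of 9 against 9 recovered 33 of 50 genes and week 8 alone, 3 against 3, 10 of 50.

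The counts below are of passed genes (edgeR unless named), and pairs give higher/lower. "Less" marks differences of acid responses. The cause of a changed count was not tested.

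Libraries of the contrast alone: in batches 1 and 2 mP4 acid 738, p53KO acid 2701, p53KO less mP4 666, mP4 pH 7 52, mP4 week 8 43, mP4 return-acid 0, mP4 return-control 1.7e+02, p53KO pH 7 0, p53KO week 8 0 and p53KO return-control 738, and in batch 3 mN10 return-acid 22, mP4 acid 1167, mP4 return-control 2512, p53KO return-acid 2682, p53KO against mP4 5027, p53R273H against p53KO 239, mN10 pH 7 1305, mP4 pH 7 966, p53KO pH 7 18 and p53R273H pH 7 2193. Sums per culture: in batches 1 and 2 mP4 acid 10, p53KO acid 1, p53KO less mP4 21, mP4 return-control 0 and p53KO return-control 1, and in batch 3 mN10 acid 2598, mN10 return-control 1644, mP4 acid 75, mP4 return-control 1.3e+02, p53KO acid 1279, p53KO return-control 1042, p53R273H return-control 3044, mP4 less mN10 499 and p53R273H less p53KO 1.0e+02. Such sums with culture as a block: in batches 1 and 2 mP4 return-acid 2397 and p53KO return-acid 1626, and in batch 3 mN10 return-acid 884, mP4 return-acid 50 and p53KO return-acid 2132. No filter: in batches 1 and 2 mP4 acid 902, p53KO less mP4 1048, mP4 return-acid 18, mP4 return-control 231, p53KO pH 7 2, p53KO week 8 89 and p53KO return-acid 244, and in batch 3 p53KO return-acid 717, p53R273H return-acid 1115, mP4 pH 7 1822 and p53KO pH 7 1028. At least 5 CPM in 3 libraries: in batches 1 and 2 mP4 pH 7 16, mP4 week 8 623, mP4 return-acid 86, mP4 return-control 781, p53KO pH 7 0 and p53KO week 8 287. DESeq2: in batches 1 and 2 mP4 return-acid 232, mP4 return-control 973, p53KO pH 7 17 (11/6, was 1/0), p53KO week 8 587 and p53KO return-acid 926, and in batch 3 mN10 return-acid 224 and mP4 return-acid 29. Protein-coding genes alone: in batches 1 and 2 mP4 pH 7 0, mP4 week 8 487 and p53KO pH 7 0. Limma on TPM: in batches 1 and 2 mP4 acid 2791 (2432/359, was 617/790), mP4 pH 7 309, mP4 week 8 4907 (4485/422, was 294/645), mP4 return-acid 72 (6/66, was 17/21), mP4 return-control 84 (26/58, was 316/195), p53KO pH 7 40 (24/16, was 1/0), p53KO return-control 2478 (1507/971, was 1920/1936), p53KO acid 2601/1100 (was 2482/2455), p53KO less mP4 592/922 (was 875/728), p53KO return-acid 79/287 (was 299/232), mP4 time 2085/3752 (was 3453/3336) and p53KO time 4272/1701 (was 2261/1895), and in batch 3 mP4 return-acid 42, p53KO return-acid 2029 (301/1728, was 607/679), p53R273H against p53KO 284 (92/192, was 75/422), mN10 return-control 914/1925 (was 1586/1722), mP4 acid 1365/761 (was 1157/1684), p53KO acid 3014/1634 (was 2251/3185), p53R273H acid 5677/2267 (was 4260/4608), p53R273H return-acid 235/2378 (was 916/948), mP4 less mN10 2037/949 (was 1399/1872), p53R273H less p53KO 1.9e+02/1.1e+02 (was 291/1.0e+02), mP4 against mN10 2435/3614 (was 3602/3398), p53KO against mP4 2729/4196 (was 4260/3922), mN10 pH 7 1725/481 (was 1182/895), mP4 pH 7 2363/535 (was 1523/1501), p53KO pH 7 1211/327 (was 710/1061) and p53R273H pH 7 2598/701 (was 2262/1819). It moved the median of all genes by 0.251 (mP4 week 8), 0.107 (p53KO pH 7, batch 3) and 0.103 (p53KO time).

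Week 8 alone: in batches 1 and 2 p53KO acid 1.7e+02 and p53KO less mP4 969. Week 1 alone: in batches 1 and 2 p53KO against mP4 6308. Week 10 alone: in batches 1 and 2 mP4 return-acid 492, mP4 return-control 211, p53KO return-acid 0 and p53KO return-control 2086, and in batch 3 mN10 return-acid 0 and p53R273H return-acid 670. Week 11 alone: in batches 1 and 2 mP4 return-acid 0, p53KO return-acid 279 and p53KO return-control 5804, and in batch 3 mN10 return-control 2134, p53KO acid 2609, p53KO return-acid 8, p53KO return-control 2120, p53R273H return-acid 1.8e+02, mP4 less mN10 1290 and p53R273H less p53KO 92. Weeks 10 and 11 alone: in batches 1 and 2 mP4 acid 287 and p53KO less mP4 556. With 1 library left out: in batches 1 and 2 mP4 acid 926 to 2192, mP4 pH 7 1.0e+02 to 1.8e+02, mP4 week 8 399 to 980, mP4 return-acid 4 to 89, mP4 return-control 212 to 1067, p53KO pH 7 0 to 1, p53KO week 8 2 to 1654, p53KO return-acid 1.6e+02 to 648 and p53KO return-control 2471 to 4067, and in batch 3 mN10 return-acid 4 to 160, mP4 acid 1604 to 2684, mP4 return-acid 0 to 11, mP4 return-control 2926 to 4521, p53KO return-acid 301 to 898, p53R273H return-acid 1016 to 2044, mP4 less mN10 1849 to 3597, p53R273H less p53KO 219 to 528, p53R273H against p53KO 243 to 819, mN10 pH 7 779 to 3037, mP4 pH 7 698 to 3364, p53KO pH 7 25 to 1945 and p53R273H pH 7 1640 to 5148. A lone library left in a group was assumed to vary like the others.

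The return-to-acid ratio of genes was 0.743 in mP4, whose genes were chosen between read-assignment sets, 0.806 and 0.725 with weeks crossed and 0.62 to 1.03 with a library left out. In p53KO it was 0.459 and ranged from -1.57 to 1.17, changing sign without 1 week 8 control. Of 275 passed list tests, 8 held with an estimated correlation. List medians changed sign in 1 test with RLE factors and 10 with TPM.

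Labels were also exchanged among the libraries of 33 contrasts, 100 splits each or all that exist (35 or 84 in smaller groups). Pairs give the count under the real labels and the highest under other splits. Splits exchange single libraries, so over several weeks they part probable cultures, and a low share does not exclude differences between cultures. The real count was reached by 1 split, the real one: in batches 1 and 2 mP4 acid 1407/265, p53KO acid 4937/2220, p53KO return-acid 531/468, p53KO against mP4 11627/5780, mP4 time 6789/4880 and p53KO time 4156/491, and in batch 3 mN10 acid 5368/4479, mN10 return-control 3308/2982, mP4 return-control 4601/3391, p53KO acid 5436/5203, p53KO return-control 4607/3559, p53R273H acid 8868/5705, p53R273H return-acid 1864/634, p53R273H return-control 4866/2789, mP4 against mN10 7000/3427, p53R273H against p53KO 497/465 and p53R273H pH 7 4081/3556. In others more splits reached it, given with the number drawn: in batches 1 and 2 p53KO less mP4 1603/2060 (3 of 100), mP4 return-acid 38/967 (13 of 100), mP4 return-control 511/1685 (2 of 100) and p53KO return-control 3856/4851 (3 of 100), and in batch 3 mN10 return-acid 69/804 (14 of 100), mP4 acid 2841/4549 (6 of 84), mP4 less mN10 3271/4815 (2 of 100), p53R273H less p53KO 393/4872 (16 of 100) and mN10 pH 7 2077/2827 (2 of 84). For mP4 acid in batch 3 and p53R273H less p53KO the share exceeds 0.05, so these counts do not stand apart from other groupings. It does for mP4 and mN10 return-acid too, but splits there break their pairing by culture and are no fair reference. Other splits called several times the real count in mP4 and mN10 return-acid, mP4 return-control, p53R273H less p53KO and p53KO week 8, which points to structure among the samples. Too few splits exist for a share below 0.05 here: in batches 1 and 2 mP4 pH 7 1.8e+02/11 (1 of 10), mP4 week 8 939/230 (1 of 10), p53KO pH 7 1/1 (2 of 10) and p53KO week 8 1.7e+02/3903 (2 of 10), and in batch 3 mP4 return-acid 0/417 (18 of 18), p53KO return-acid 1286/217 (1 of 18) and p53KO against mP4 8182/1129 (1 of 10). Splits were not drawn for mP4 and p53KO at pH 7 in batch 3.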

Other observations

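The p53 hypothesis below was written before its test, and this paragraph's genes were picked after their values were seen. Of 6 contrasts of return against acid, no gene passed in more than 4 without pairing by culture. That limit holds for the unpaired test alone, which called 38 and 0 genes in mP4 and 69 in mN10, against 2397, 50 and 884 with culture as a block. Those higher on return in 4 were the tRNA ligase Aars (0.21 to 0.59 over the 6), Itfg2 (0.31 to 0.54) and the nuclease Mus81 (0.29 to 0.60). Coding genes lower in 4 included the basement membrane genes Tinag (-1.77 to -0.78) and Npnt (-0.78 to -0.32) and the recombination gene Rdm1 (-1.11 to -0.74). Of the 62 and 100 genes that passed higher and lower in both p53KO contrasts and in p53R273H, 45 and 59 kept their sign in all 6.

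If wild-type p53 drove the fall of its targets on return, lines with altered Trp53 should fall less. The list differed that way in each pair. Its fall, already seen in these mP4 and mN10 libraries, favours that sign. Its median difference was 0.298 for p53KO less mP4 in batches 1 and 2 (27 of 30 genes higher), 0.337 for the same pair in batch 3 (20 of 29) and 0.263 for p53R273H less mN10 (24 of 29). The limma camera p with an estimated correlation were 0.00263, 0.00505 and 0.00108. Adjusted over the 27 lists by camera these were 0.0709, 0.11 and 0.0293, so 1 of 3 passed. In p53KO single targets rose on return (Cdkn1a 1.32 in batch 3), which that idea does not predict. For p53KO less mP4 in batch 3 no list passed by camera with an estimated correlation: NF-kB, mitosis and DNA replication had the same adjusted value of 0.11. The lines differ in more than Trp53, and p53R273H and mN10 also differ in Kras, so the gene was not isolated.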
